A study of Mus musculus with 9 samples.

How the data were processed

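Cortical kidney RNA from wild-type and Notch3-/- mice was measured on 9 Agilent one-colour arrays, each hybridised with Cy3-labelled RNA of 1 kidney sample, in 4 groups of 2, 2, 3 and 2 arrays given by the labels. Per the file headers, the spots were extracted with Feature Extraction 10.7.3.1, while the submitters' processing notes name version 10.5. The processed signal is an intensity that, per the file headers, was background-subtracted but not normalized between arrays, and the median spot and background signals are intensities with no correction. The deposited value table holds log2 values of the authors, with column medians of 7.02 to 7.05. Set against the processed signals over 39429 probes it gave correlations of 0.971 to 0.986 per array. It is on a log2 scale and not centred per gene, and the authors' method of normalization is not given in the sources used here.

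For the comparisons, spots marked as outliers (117 to 204 per array) were left out, log2 of the processed signal was taken relative to the array's 75th percentile over the 43020 non-control spots, and spots of a probe were averaged. Probes well above background on at least 2 of the 9 arrays were kept, 29336 of 39429. Accessions without versions were matched to a reference gene table of assembly GRCm38.p6, which named 27234 probes with 20659 symbols and left 12195 unnamed. The grid of the arrays was built on mm9, so no coordinates are given. The brightest probe stood for each gene, which left 23878 genes and unnamed transcripts, 16603 of them with a symbol. Of 4371 genes with several probes, 8, 9, 1, 0 and 0 had probes called in opposite directions in the 5 comparisons, taken in the order of the results. No column of per-sample values was left out.

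Group means were fitted to all 9 arrays with limma 3.58.1 in R 4.3.3, with 5 residual degrees of freedom, and p-values were adjusted by Benjamini and Hochberg at a threshold of 0.05. For 35 gene lists, camera compared the members with all other genes at a preset inter-gene correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry, which asks whether the members of a list move one way, were run beside it. The groups, lists, tests of the comparisons, the rule for naming genes and the alternatives were chosen before the data were examined, except a term for the arrays with high Xist, a fit without them and a crossed replicate block, which were added after seeing the data. Under that rule a comparison names the 12 largest changes in each direction among genes past the threshold with a symbol, no overlap between the arrays of both groups and a signal well above background in the higher group. It also names up to 4 members of each list with the smallest adjusted p, and in every comparison Notch1, Notch2, Notch3, Notch4, Jag1, Hes1, Hey1, Heyl, Col1a1, Col3a1, Acta2, Fn1, Tgfb1, Ccl2, Havcr1 and Lcn2. Where under 5 genes passed in a direction, the 5 with the smallest p could be named as not passing. Xist, Ddx3y and Cyp11b1 were named after their values were seen.

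A gene well above background on no array of a group has only a bound there. Its fold is given as at least the brighter group's mean over the dimmer group's, where each dim array counts at the higher of the gene's own signal and the lowest signal among probes well above background.

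The arrays lay on 5 slides. The wild-type UUO arrays shared slide 3, the wild-type healthy arrays lay on slides 1 and 2, and slide 4 held the 3 Notch3-/- UUO arrays and Notch3-/- healthy replicate 1, with replicate 2 on slide 5. Wild-type and Notch3-/- arrays were scanned in separate campaigns, so genotype and campaign cannot be told apart. Slide was used as a random block over all arrays, where its consensus correlation was 0.363, and as a fixed block within the Notch3-/- arrays. Further alternatives were quantile normalization, normexp background correction with an offset of 50, the authors' value table, other probe filters, the mean of a gene's probes, trended and robust moderation, array weights, a replicate block, a threshold of 0.01, a required 2-fold change, fits of only the groups compared and leaving out each array. Normexp used median spot signals, since the files used here hold no mean signals.

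The steps were tested on simulated data in which 200 of 23878 genes were changed. Of genes changed by a log2 of 2, 79.1% were recovered for wild-type UUO versus healthy, 71.6% for Notch3-/- UUO versus healthy, 61.2% between the UUO groups, 58.2% between the healthy groups and 35.8% for the difference of responses. At a log2 of 1 the shares were 25.4%, 37.3%, 37.3%, 19.4% and 7.46%. Between 3 and 11 unchanged genes were called. Noise was drawn independently for each gene and array, without effects of slide, campaign or sex. Far fewer genes were changed than obstruction called, so recovery and false calls in the real arrays may differ.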

Results

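Kidney cortex RNA from wild-type mice and from mice lacking Notch3, a receptor of the Notch family that vascular smooth muscle cells and pericytes are known to carry, was measured on 9 one-colour microarrays. The injury model was unilateral ureteral obstruction (UUO), in which 1 ureter is tied off and the kidney behind it becomes inflamed and fibrotic. Kidneys were taken 5 days after ligation from animals 12 to 16 weeks old. The arrays comprised 2 wild-type healthy, 2 wild-type UUO, 2 Notch3-/- healthy and 3 Notch3-/- UUO kidneys. The design text speaks of the untouched opposite kidneys as the comparison, but the labels do not say which healthy array came from which animal, nor that arrays of a group came from separate animals. If they did not, the p-values measure only a spread that may be technical. Between 28099 and 31496 of the 43020 non-control spots, or 65.3% to 73.2%, lay well above background per array, and no spot was saturated. The number of arrays limits the precision. Values below are log2 signal relative to each array's 75th percentile, differences are log2 fold changes ± SE from limma, and adjusted p-values follow Benjamini and Hochberg over 23878 tested genes and unnamed transcripts.

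Notch3 was low in all 5 arrays labelled Notch3-/-. Its signal was -0.38 ± 0.17 (SD, n = 2) in wild-type healthy and 0.80 ± 0.17 (SD, n = 2) in wild-type UUO kidneys. It was -5.18 ± 0.29 (SD, n = 2) in Notch3-/- healthy and -3.89 ± 0.36 (SD, n = 3) in Notch3-/- UUO kidneys. The difference between the genotypes was -4.81 ± 0.27 in healthy kidneys (limma, adjusted p = 0.00311) and -4.68 ± 0.24 in obstructed kidneys (limma, adjusted p = 0.00401). The single Notch3 probe stayed well above background on all 9 arrays, and whether it lies in the deleted part of the gene is not given in the sources used here. Obstruction raised its signal by 1.17 ± 0.27 in wild-type kidneys (limma, adjusted p = 0.0224) and by 1.30 ± 0.24 in Notch3-/- kidneys (limma, adjusted p = 0.0148).

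**Figure D1:**
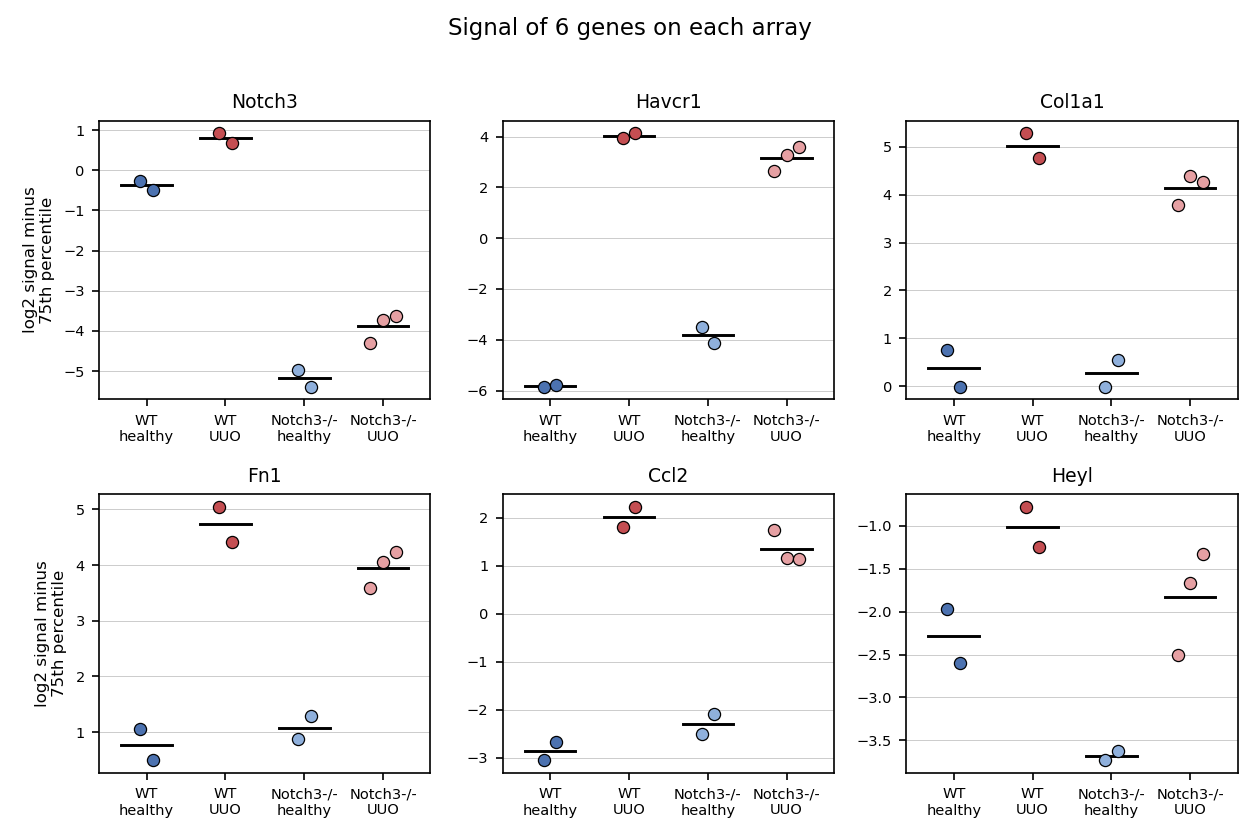
Signal of 6 genes on each of the 9 arrays, as log2 signal minus the array's 75th percentile, by group (WT, wild-type); each point is an array and each bar the group mean. Notch3 lies between -5.39 and -3.63 on the Notch3-/- arrays and between -0.50 and 0.92 on the wild-type arrays, while Havcr1, Col1a1, Fn1 and Ccl2 are higher in every obstructed kidney than in any healthy kidney.

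The first comparison asked what 5 days of obstruction changed in wild-type kidneys. Markers of tubular injury, extracellular matrix genes, inflammatory genes and cell cycle genes rose, while genes of tubular transport and energy metabolism fell. Havcr1, which encodes the injury marker KIM-1, rose by 9.85 ± 0.34 (limma, adjusted p = 0.000243), and the transcription factor Sox9 rose by 5.31 ± 0.17 (limma, adjusted p = 0.000243). Havcr1 and Sox9 were well above background on 1 of the 2 healthy arrays. Col1a1, which encodes a chain of type I collagen, rose by 4.65 ± 0.36 (limma, adjusted p = 0.00102). In all, 3373 genes rose and 2806 fell, with 2 arrays on each side.

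All but 3 of 26 measured tubular injury markers rose (23; 26 adjusted over the list alone), with a median log2 fold change of 2.64. They included Lcn2, which encodes the iron-binding protein NGAL, at 6.48 ± 0.50 and the adhesion molecule Vcam1 at 4.61 ± 0.24. Of 37 extracellular matrix genes, 31 rose (35 adjusted over the list alone), among them Col1a2 at 3.69 ± 0.27, Col3a1 at 4.35 ± 0.54 and fibronectin, Fn1, at 3.96 ± 0.33. Of 35 matrix remodelling genes, 23 rose and 3 fell (24 and 4 adjusted over the list alone). The inhibitor Timp1 rose by 6.57 ± 0.40 and the protease Mmp7, well above background on 1 of the 2 healthy arrays, by 5.98 ± 0.42. Of 20 fibroblast, myofibroblast and pericyte markers, 11 rose (13 adjusted over the list alone); Acta2, the smooth muscle actin of myofibroblasts, rose by 1.43 ± 0.38 (limma, adjusted p = 0.0356). Tgfb1 rose by 1.78 ± 0.25 (limma, adjusted p = 0.00553), among 15 of 28 TGF-beta and PDGF genes that rose and 1 that fell (18 and 1 adjusted over the list alone). With the inter-gene correlation preset at 0.01, camera placed these 5 lists above the other genes, at adjusted p-values from 1.26e-15 to 1.34e-05. None kept its call with an estimated correlation, where the adjusted p-values were 0.146 to 0.246.

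Inflammatory lists moved in the same direction. Of 29 measured chemokines, 19 rose and 2 fell (20 and 2 adjusted over the list alone). The monocyte attractant Ccl2 rose by 4.87 ± 0.29, and the neutrophil attractant Cxcl5, not well above background in healthy kidneys, was at least 40.8-fold higher. Of 26 macrophage and monocyte markers, 20 rose and 1 fell (21 and 1 adjusted over the list alone), with a median of 2.82. The fractalkine receptor Cx3cr1 rose by 3.52 ± 0.24, and lysozyme, Lyz2, was at least 96.6-fold higher. T and NK cell markers rose in 11 of 22 cases (16 adjusted over the list alone), and antigen presentation genes in 15 of 18 (16 adjusted over the list alone), including H2-Ab1 at 2.21 ± 0.19. Interferon response genes rose in 24 of 31 cases (25 adjusted over the list alone), with Oas1a at 2.43 ± 0.15. Cell cycle genes had the lowest camera p of the 35 lists: 32 of 34 rose, by either adjustment, including the mitotic cyclin Ccnb1 at 4.26 ± 0.30 and Mki67 at 3.99 ± 0.35. These 6 lists had camera adjusted p-values from 1.94e-16 to 1.68e-06, and adjusted p-values of 0.146 to 0.21 with an estimated correlation.

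Genes of the working tubule fell. Of 44 proximal tubule transporters and enzymes, 29 fell and 1 rose (37 and 1 adjusted over the list alone), with a median of -1.74. The organic anion transporter Slc22a8 had a log2 fold change of -4.36 ± 0.50 (limma, adjusted p = 0.0027), and Pck1, an enzyme of gluconeogenesis, of -2.51 ± 0.25. Of 31 loop of Henle, distal tubule and collecting duct markers, 17 fell (22 fell and 1 rose adjusted over the list alone); Egf stood at -5.22 ± 1.07 and Calb1, which encodes a calcium-binding protein, at -4.52 ± 0.59. Of 34 oxidative phosphorylation and citrate cycle genes, 30 fell (33 adjusted over the list alone), and of 33 fatty acid oxidation genes, 23 fell (27 adjusted over the list alone). Sdhc, a subunit of complex II, stood at -1.13 ± 0.13, and the thiolase Acaa2 at -1.86 ± 0.15. The carboxylesterase Ces1g, not well above background in the obstructed kidneys, was at least 61.4-fold lower there. The 4 lists had camera adjusted p-values from 6.05e-13 to 4.67e-08, and adjusted p-values of 0.148 to 0.243 with an estimated correlation.

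Within the Notch pathway, obstruction of wild-type kidneys raised Notch3 and Notch2, the latter by 0.74 ± 0.13 (limma, adjusted p = 0.0105). It lowered the ligand Dll1, whose log2 fold change was -0.80 ± 0.17 (limma, adjusted p = 0.0188). Notch4 at -0.07 ± 0.15, Jag1 at 0.14 ± 0.28, Hes1 at 0.51 ± 0.40, Hey1 at -0.77 ± 0.25 and Heyl at 1.27 ± 0.41 did not pass, with limma adjusted p-values from 0.0604 to 0.772. Notch1 at -2.01 ± 0.73 did not pass either (limma, adjusted p = 0.0859), and its healthy arrays stood at 0.94 and -1.55. Of 10 receptors and ligands, 2 rose and 1 fell; of 26 pathway components, 4 rose and 3 fell, among them Dtx4 at 2.28 ± 0.32 and Numbl at 2.12 ± 0.33. Neither list passed with camera (adjusted p = 0.846 and 0.269). The wild-type UUO arrays shared a slide, and the healthy arrays lay on a slide each. With slide as a random block the counts were 1703 and 703, and fitting only these groups gave a total of 3499. Leaving out wild-type UUO replicate 1 or 2 gave totals of 1287 and 2204.

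The second comparison asked the same of kidneys without Notch3. Obstruction again raised injury, matrix and immune genes and lowered transport and metabolic genes: 3171 genes rose and 3322 fell, with 3 arrays against 2. Havcr1 rose by 6.98 ± 0.31 (limma, adjusted p = 0.000417), Col1a1 by 3.87 ± 0.33 (limma, adjusted p = 0.000918) and Ccl2 by 3.65 ± 0.26 (limma, adjusted p = 0.00066). Egf fell by 3.55 (SE 0.98; limma, adjusted p = 0.0381). Of the genes called, 2284 rose in both genotypes, where independent lists of these sizes would share 447.9, and 2010 fell in both, where they would share 390.4. There were 11 calls in opposite directions. Across genes, which are not independent replicates, the log2 fold changes of both genotypes correlated with r = 0.768 (Spearman 0.748), and the slope of the Notch3-/- on the wild-type changes was 0.734. Error in the wild-type changes lowers such a slope, so it does not show a weaker response in Notch3-/- kidneys.

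**Figure D2:**
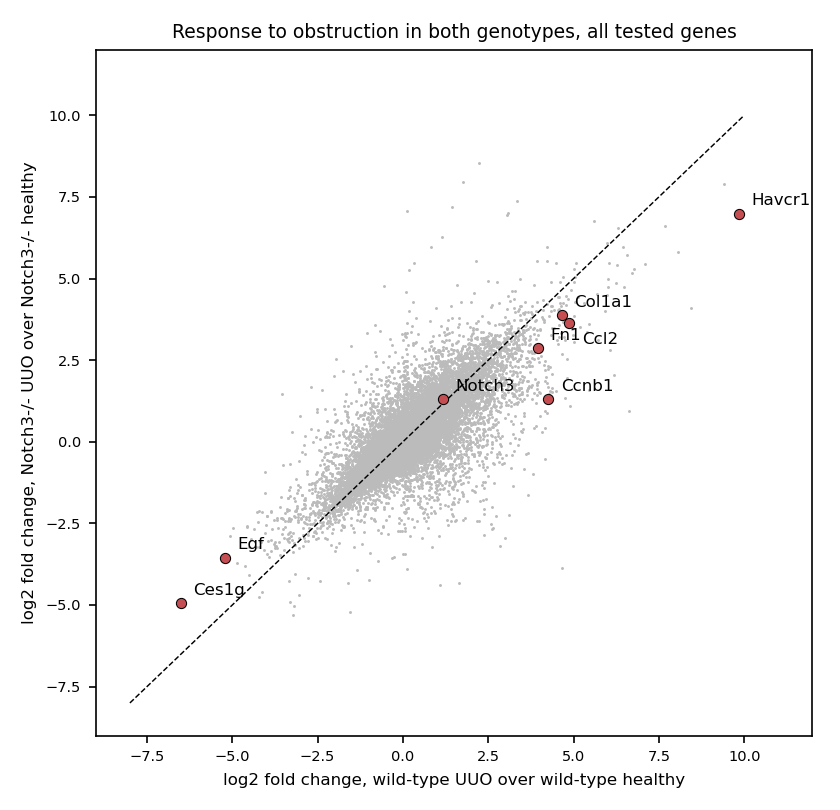
Log2 fold change of obstructed over healthy kidneys for each tested gene, in wild-type mice on the horizontal axis and in Notch3-/- mice on the vertical axis; grey points are genes, red points the 8 named ones, and the dashed line marks equal changes. The changes correlate with r = 0.768 at a slope of 0.734, and Havcr1, at 9.85 and 6.98, and Ccnb1, at 4.26 and 1.31, lie below the line. Error in the wild-type changes lowers the slope, so it does not show a weaker response in Notch3-/- mice.

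Of 37 extracellular matrix genes, 33 rose (34 adjusted over the list alone), with Col1a2 at 3.13 ± 0.24, Col3a1 at 4.01 ± 0.50 and Fn1 at 2.87 ± 0.30. Of 35 matrix remodelling genes, 24 rose and 1 fell (26 and 2 adjusted over the list alone), with Timp1 at 5.73 ± 0.36, and of 20 fibroblast and pericyte markers 13 rose (14 adjusted over the list alone). Acta2 rose by 1.93 ± 0.35 (limma, adjusted p = 0.0131), and Tgfb1 rose 3.99-fold (limma, adjusted p = 0.00272). Tubular injury markers rose in 20 of 26 cases (22 adjusted over the list alone), with Lcn2 at 4.73 ± 0.46 and Sox9 at 4.25 ± 0.15. Of 31 interferon response genes 29 rose (30 adjusted over the list alone), with Oas1a at 2.10 ± 0.14. Of 22 T and NK cell markers 17 rose (19 adjusted over the list alone), including the T cell kinase Zap70 at 2.38 ± 0.15. Macrophage markers rose in 20 of 26 cases and fell in 2, by either adjustment, and Itgam of this list had probes called in opposite directions. The scavenger receptor Msr1, not well above background in healthy kidneys, was at least 3.78-fold higher, and Cd14 rose by 4.28 ± 0.29. Cell cycle genes rose in 21 of 34 cases (30 rose and 1 fell adjusted over the list alone), with Plk1 at 1.56 ± 0.28. Camera adjusted p-values of these 8 lists ran from 6.5e-19 to 1.03e-07, and with an estimated correlation the adjusted p-values were 0.104 to 0.223.

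All 34 oxidative phosphorylation and citrate cycle genes fell by their brightest probes and by either adjustment, with a median of -1.08 and Sdhc at -1.19 ± 0.12. Ogdh, a member of this list, had probes called in opposite directions. Proximal tubule genes fell in 34 of 44 cases (40 fell and 1 rose adjusted over the list alone), with the endocytic receptor Cubn at -1.43 ± 0.25 and Slc13a3 at -1.88 ± 0.30. Fatty acid oxidation genes fell in 26 of 33 cases (30 adjusted over the list alone), with Decr1 at -0.87 ± 0.11. Loop of Henle and distal markers fell in 17 of 31 cases (20 adjusted over the list alone), with Calb1 at -3.21 ± 0.54 and Pvalb at -4.60 ± 0.75. These 4 lists had camera adjusted p-values from 2.88e-12 to 7.24e-07, and adjusted p-values of 0.164 to 0.239 with an estimated correlation. In the Notch pathway, Dll4 at 0.70 ± 0.17, Heyl at 1.84 ± 0.37 and the modifier Lfng at 2.01 ± 0.30 rose (limma, adjusted p = 0.0273, 0.0177 and 0.00743), and Notch2 at 0.39 ± 0.12 passed narrowly (limma, adjusted p = 0.0498). Notch1 at -0.36 ± 0.67, Notch4 at 0.16 ± 0.14, Jag1 at 0.24 ± 0.25, Hes1 at 0.02 ± 0.37 and Hey1 at -0.22 ± 0.23 did not pass, with limma adjusted p-values from 0.418 to 0.971. Dll4 stood at 0.00 with normexp background correction.

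The Notch3-/- UUO arrays were not alike. Xist, the RNA that coats the inactive X chromosome of females, stood at 0.18 and 0.00 on replicates 2 and 3 and at -8.64 on replicate 1, and the Y-linked gene Ddx3y at -3.80 and -3.67 against -0.03. The other 6 arrays had Xist at -5.71 or below and Ddx3y at -0.26 or above, although the design text calls the mice matched by sex. Replicates 2 and 3 also carried 1 transcript of the adrenal cortex: Cyp11b1, named here after its values were seen, stood at 4.69 and 5.15 against -4.14 or below elsewhere. Along the first principal component, which held 54.1% of the variance, replicate 1 stood at 11.3 and the other UUO arrays between 58.6 and 92.4. Without replicates 2 and 3, an alternative chosen after seeing the data that leaves 1 UUO array, 402 genes were called in place of 6493.

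The slide that held all 3 Notch3-/- UUO arrays and 1 healthy array gave 739 rises and 48 falls when fitted alone, and so did slide as a fixed block. Within that slide 24 lists were placed higher and 5 lower by camera, against 22 and 6 with all arrays, and Col1a1, Havcr1 and Ccl2 stayed past the threshold. The lone healthy array of that slide is assumed there to vary like the 3 UUO arrays, from which the spread comes. The total was 1226 or 1796 without Notch3-/- healthy replicate 1 or 2, 1770 or 1768 without Notch3-/- UUO replicate 2 or 3, 3815 with only these groups fitted and 11440 with array weights. With normexp the share of calls that were rises was 28.2% against 48.8%, and the median of all genes lay at -0.23 against -0.07.

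The third comparison set obstructed kidneys of both genotypes side by side, to ask which fibrosis genes, cytokines, chemokines and Notch family members differ without Notch3. Of single genes, 19 were higher and 52 lower in Notch3-/- UUO kidneys, with 3 arrays against 2, and of these 11 and 18 had a gene symbol. That count depended on the setting: it was 4374 with array weights and 603 with only these groups fitted. In alternatives chosen after seeing the data it was 131 with a term for the 2 arrays with high Xist and 0 without them, which leaves 1 Notch3-/- UUO array (limma, smallest adjusted p = 0.0576, with 3404 at an unadjusted p under 0.05). Besides Notch3, the keratin Krt14 was lower by a log2 fold change of -2.66 ± 0.21 (limma, adjusted p = 0.0155), the nuclear receptor Nr1i3 by -1.82 ± 0.17 (limma, adjusted p = 0.0256) and the synaptic protein gene Rims1 by -2.90 ± 0.24 (limma, adjusted p = 0.0155). The desmosome protein gene Pkp1, not well above background in Notch3-/- UUO kidneys, was at least 8.43-fold lower there.

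Among the genes higher without Notch3, the class I histocompatibility gene H2-Q8 differed by 1.63 ± 0.17 (limma, adjusted p = 0.0315) and Apol9b by 1.35 ± 0.17 (limma, adjusted p = 0.0413). Treml1, a gene of platelets, differed by 1.75 ± 0.18, Nap1l5 by 2.03 ± 0.22 and Uroc1, an enzyme of histidine breakdown, by 1.43 ± 0.16. Ccnb1ip1 and Dscaml1 were not well above background in wild-type UUO kidneys and were at least 1.47-fold and 2.81-fold higher without Notch3. The value of Dscaml1 is uncertain, since its probes were called in opposite directions and their mean gave -1.21 (limma, adjusted p = 0.126).

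Of the fibrosis genes, Col1a1 at -0.88 ± 0.33, Col3a1 at -0.62 ± 0.50, Fn1 at -0.78 ± 0.30 and Acta2 at -1.05 ± 0.35 did not pass, with limma adjusted p-values of 0.252, 0.573, 0.264 and 0.213. Tgfb1 differed by -0.15 ± 0.23 (limma, adjusted p = 0.786), Ccl2 by -0.66 ± 0.26 (limma, adjusted p = 0.274), Havcr1 by -0.85 ± 0.31 (limma, adjusted p = 0.241) and Lcn2 by -0.20 ± 0.46 (limma, adjusted p = 0.866). As a list the 37 extracellular matrix genes lay lower without Notch3, with a median of -0.67 (camera, adjusted p = 1.86e-08; adjusted p = 0.754 with an estimated correlation). No member passed over all genes and 1 was lower adjusted over the list alone. Col6a2 at -1.48 ± 0.28 came nearest (limma, adjusted p = 0.0891). The 20 fibroblast and pericyte markers had a median of -0.72 and the 35 matrix remodelling genes of -0.41 (camera, adjusted p = 2.64e-05 and 0.000223; adjusted p = 0.754 for both with an estimated correlation). Tubular injury markers had a median of -0.38 (camera, adjusted p = 0.00122; adjusted p = 0.754 with an estimated correlation), with Sox9 at -1.08 ± 0.15 (limma, adjusted p = 0.0576). On the arrays, the median of the matrix list was 1.65 and 1.35 in wild-type UUO kidneys, and -0.06, 0.81 and 1.15 in Notch3-/- UUO kidneys, of which replicate 1 was the lowest. The remodelling list stood at 0.43 and 0.07 against -0.58, 0.41 and 0.61, and the injury list at 3.51 and 3.05 against 2.23, 3.21 and 3.42, so that in both lists replicates 2 and 3 lay within the wild-type range or above it. Without replicate 1 the call of the injury list ended, at a median of -0.21 (camera, adjusted p = 0.188). The matrix, fibroblast and remodelling lists still passed without it, at medians of -0.44, -0.58 and -0.27 (camera, adjusted p = 0.000119, 0.00188 and 0.0242). That fit sets only Notch3-/- UUO arrays with high Xist against wild-type arrays without it. These lists also lay lower without Notch3 in healthy kidneys, at medians of -0.60, -0.93 and -0.58 (camera, adjusted p = 2.86e-05, 1.09e-05 and 9.95e-06). Differences between their responses to obstruction did not pass, at medians of -0.16, 0.16 and 0.10 (camera, adjusted p = 0.636, 0.416 and 0.314). As list medians, the lower level was thus seen in healthy kidneys too. With an estimated correlation the healthy shifts did not pass (camera, adjusted p = 0.602, 0.496 and 0.466). Responses whose difference did not pass are not shown to be equal. Of the single genes above, Col1a1, Col3a1 and Fn1 differed less between the healthy groups and Acta2 differed more, and none passed there.

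Interferon response genes went the other way. Their median was 0.70 higher in Notch3-/- UUO kidneys (camera, adjusted p = 1.07e-11; adjusted p = 0.754 with an estimated correlation). No member passed over all genes, and 10 of 31 were higher adjusted over the list alone. Isg15 at 1.39 ± 0.20, Oasl1 at 1.17 ± 0.18 and Oas1a at 0.84 ± 0.14 had limma adjusted p-values of 0.0618, 0.0631 and 0.0637. All 3 Notch3-/- UUO arrays, at list medians of 1.56, 2.06 and 1.88, lay above both wild-type UUO arrays at 1.23 and 1.11. Chemokines and cytokines did not shift as lists (camera, adjusted p = 0.586 and 0.496), and their members nearest to passing were Ccl24 at -1.10 ± 0.19 and Ifng at 1.59 ± 0.26 (limma, adjusted p = 0.0735 and 0.0637), the latter well above background on 1 of the 2 wild-type UUO arrays. Macrophage markers and T and NK cell markers did not pass either (camera, adjusted p = 0.473 and 0.162).

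Of the remaining Notch receptors, Notch1 at -0.52 ± 0.67, Notch2 at -0.27 ± 0.12 and Notch4 at -0.34 ± 0.14 did not pass, with limma adjusted p-values of 0.741, 0.316 and 0.282. Jag1 at 0.04 ± 0.25, Hes1 at -0.45 ± 0.37, Hey1 at 0.12 ± 0.23 and Heyl at -0.82 ± 0.37 did not pass, at limma adjusted p-values of 0.326 to 0.952. The list of 10 receptors and ligands, which includes Notch3, had a median of -0.30 (camera, adjusted p = 0.0487; adjusted p = 0.754 with an estimated correlation). Its only member past the threshold over all genes was Notch3, the gene knocked out. The list was not tested without Notch3, so its call does not show that the other receptors and ligands were lower. Loop of Henle and distal markers lay higher by a median of 0.51 and oxidative phosphorylation genes by 0.21 (camera, adjusted p = 6.7e-05 and 0.00625; adjusted p = 0.754 and 0.823 with an estimated correlation). Acute-phase genes lay lower by a median of -0.68 (camera, adjusted p = 0.00703; adjusted p = 0.754 with an estimated correlation). Without Notch3-/- UUO replicate 1 the median was 0.29 for the distal markers, which still passed, and the calls of receptors and ligands, oxidative phosphorylation and acute-phase genes ended (camera, adjusted p = 0.274, 0.984 and 0.206). They ended without wild-type UUO replicate 1 as well (camera, adjusted p = 0.152, 0.289 and 0.152), and that of receptors and ligands also without Notch3-/- UUO replicate 2 (0.054) or either Notch3-/- healthy array (0.0674).

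Urothelium markers had a median of -2.73 (camera, adjusted p = 6.07e-05; adjusted p = 0.754 with an estimated correlation), and Krt14 belongs to that list. Adipocyte, adrenal and muscle markers did not pass as a list (camera, adjusted p = 0.426), with a median difference of -0.85 but a mean of 0.55. On the arrays their median stood at -1.07 and -1.97 in wild-type UUO and at -6.26, 1.18 and 2.03 in Notch3-/- UUO kidneys. All wild-type arrays were scanned in a different campaign from all Notch3-/- arrays, so genotype and campaign cannot be told apart, and with slide as a random block 3 genes were called in place of 71, Notch3 among them. Leaving out single arrays gave 7 and 1 calls without wild-type UUO replicate 1 and 2, 328, 5 and 2 without Notch3-/- UUO replicate 1, 2 and 3, 633 without either wild-type healthy array and 26 without either Notch3-/- healthy array. Higher genes made up 26.8% of the calls, against 50.4% of 141 with quantile normalization, 47.4% of 213 with normexp, 48.0% of 419 with both and 52.3% of 298 in the authors' value table.

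**Figure D3:**
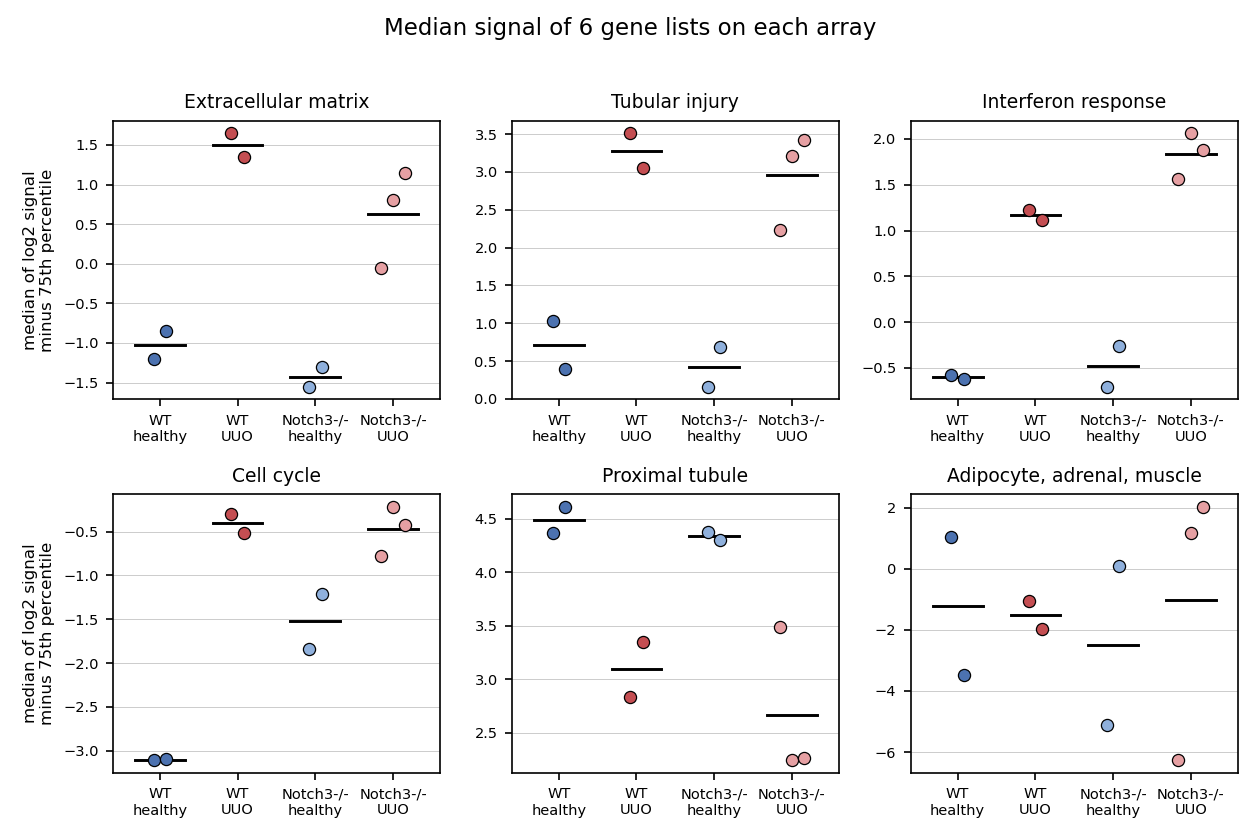
Median signal of 6 gene lists on each of the 9 arrays, as log2 signal minus the array's 75th percentile, by group (WT, wild-type); each point is an array and each bar the mean of the points. Matrix and injury lists are higher in every UUO array than in any healthy array, cell cycle genes lie at -3.11 and -3.10 in wild-type healthy against -1.84 and -1.21 in Notch3-/- healthy kidneys, and markers of fat, adrenal and muscle scatter from -6.26 to 2.03.

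The fourth comparison set the healthy kidneys of both genotypes side by side, as the background against which the obstructed kidneys are read. In all, 57 genes were higher and 65 lower in Notch3-/- healthy kidneys, with 2 arrays on each side. Ccnb1 differed by 3.01 ± 0.30 (limma, adjusted p = 0.0248), Cdc20, an activator of mitotic exit, by 2.77 ± 0.31 (limma, adjusted p = 0.0253) and the spindle protein gene Prc1 by 2.88 ± 0.40 (limma, adjusted p = 0.0445). The heat shock gene Hspa1a differed by -2.62 ± 0.26 (limma, adjusted p = 0.0248) and Igfbp3 by -2.45 ± 0.31 (limma, adjusted p = 0.0347).

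Of 34 cell cycle genes, 5 were higher over all genes and 24 adjusted over the list alone, with a median of 1.58 (camera, adjusted p = 7.96e-19; adjusted p = 0.39 with an estimated correlation). The mitotic kinase Melk and Iqgap3 were not well above background in wild-type healthy kidneys and were at least 4.94-fold and 3.48-fold higher without Notch3. Interferon response genes had a median of 0.28 and apoptosis and p53 genes of 0.36 (camera, adjusted p = 0.0178 for both; adjusted p = 0.757 and 0.602 with an estimated correlation), with Oas1a at 1.17 ± 0.15 and Bax at 1.04 ± 0.14 past the threshold. Both list calls ended without wild-type healthy replicate 2 (camera, adjusted p = 0.353 and 0.152) and without Notch3-/- healthy replicate 2 (camera, adjusted p = 0.979 and 0.169). Havcr1 stood higher by 2.01 ± 0.34 without passing (limma, adjusted p = 0.068). Lcn2 at 1.54 ± 0.50, Acta2 at -1.56 ± 0.38, Ccl2 at 0.56 ± 0.29, Tgfb1 at -0.37 ± 0.25, Fn1 at 0.31 ± 0.33, Col3a1 at -0.28 ± 0.54 and Col1a1 at -0.10 ± 0.36 did not pass either, with limma adjusted p-values from 0.127 to 0.915.

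The 22 T and NK cell markers had a median of -0.73, with 1 lower over all genes and 12 adjusted over the list alone (camera, adjusted p = 2.05e-08; adjusted p = 0.35 with an estimated correlation). The 18 endothelial markers had a median of -0.78, with none past the threshold over all genes and 10 lower adjusted over the list alone (camera, adjusted p = 3.57e-08; adjusted p = 0.35 with an estimated correlation). Tek, the angiopoietin receptor, at -1.50 ± 0.22 and Plvap at -1.37 ± 0.21 came nearest (limma, adjusted p = 0.0503 and 0.0577). Fibroblast and pericyte markers had a median of -0.93 and extracellular matrix genes of -0.60 (camera, adjusted p = 1.09e-05 and 2.86e-05; adjusted p = 0.496 and 0.602 with an estimated correlation). The median of matrix remodelling genes was -0.58 (camera, adjusted p = 9.95e-06, and 0.466 with an estimated correlation). Podocyte markers had a median of -0.31 (camera, adjusted p = 0.000666; adjusted p = 0.35 with an estimated correlation), with Podxl at -1.33 ± 0.21 (limma, adjusted p = 0.0631). The leptin gene Lep and the chemokine Ccl24, not well above background without Notch3, were at least 2.01-fold and 1.83-fold lower. Lep belongs to the adipocyte, adrenal and muscle markers, whose median of -1.39 did not pass (camera, adjusted p = 0.0642). On the arrays that list scattered within groups, at 1.055 and -3.461 in wild-type and -5.099 and 0.109 in Notch3-/- healthy kidneys. Urothelium markers lay lower as well, at a median of -2.73 (camera, adjusted p = 0.000942, and 0.555 with an estimated correlation). Without wild-type healthy replicate 1 they stood at -1.12 with the call ended (camera, adjusted p = 0.171). The 10 Notch receptors and ligands, which include Notch3, had a median of -0.42 (camera, adjusted p = 0.000539; adjusted p = 0.35 with an estimated correlation; fry, adjusted p = 0.0253). Of these 1, Notch3 itself, was lower over all genes and 5 adjusted over the list alone, and Notch1 at -2.17 ± 0.73 did not pass (limma, adjusted p = 0.204). The list was not tested without Notch3, the gene knocked out. Notch2 at 0.08 ± 0.13, Notch4 at -0.57 ± 0.15, Jag1 at -0.06 ± 0.28, Hes1 at 0.04 ± 0.40, Hey1 at -0.43 ± 0.25 and Heyl at -1.39 ± 0.41 did not pass either, with limma adjusted p-values from 0.141 to 0.977. Fitting only these groups called 0 genes in place of 122 (limma, smallest adjusted p = 0.284, with 2428 at an unadjusted p under 0.05), array weights called 4, and trended robust moderation 236. With slide as a random block 12 genes were called; leaving out single arrays gave 217 without wild-type healthy replicate 1, 26 without either wild-type UUO array, 20 and 6 without Notch3-/- UUO replicate 2 and 3, and 60 and 1 without Notch3-/- healthy replicate 1 and 2. Higher genes made up 46.7% of the calls against 59.6% with normexp, where the median of all genes lay at 0.18 against 0.06.

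The last comparison tested whether obstruction changed genes by a different amount without Notch3. In this contrast an equal shift of all arrays of a scan campaign cancels. A campaign effect of unlike size in healthy and obstructed kidneys does not cancel. Neither does an effect of sex, since only Notch3-/- UUO arrays had high Xist. No single gene passed with limma, where the smallest adjusted p was 0.162, and 1705 genes had an unadjusted p under 0.05. Lists differed. Cell cycle genes rose less in Notch3-/- kidneys, with a median difference of -1.60 and 22 of 34 lower adjusted over the list alone (camera, adjusted p = 1.19e-21; adjusted p = 0.346 with an estimated correlation). T and NK cell markers rose more, by a median of 1.15 with 11 of 22 adjusted over the list alone (camera, adjusted p = 2.48e-12; adjusted p = 0.342 with an estimated correlation). In both lists the genotypes differed mainly in the healthy kidneys, with 2 arrays on each side. Medians there were 1.58 for cell cycle genes and -0.73 for T and NK cell markers, against 0.04 and 0.27 in obstructed kidneys.

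Of single genes, Ccnb1 differed by -2.96 ± 0.41 and Cdc20 by -2.49 ± 0.42 (limma, adjusted p = 0.261 and 0.282). The chemokine receptor Cxcr6 at 1.77 ± 0.27 and Zap70 at 1.25 ± 0.23 pointed the other way (limma, adjusted p = 0.261 and 0.329). Havcr1 at -2.87 ± 0.46 and Sox9 at -1.06 ± 0.22 did not pass (limma, adjusted p = 0.271 and 0.382). The extracellular matrix list did not pass (median difference -0.16; camera, adjusted p = 0.636), nor did Col1a1 at -0.78 ± 0.48, Fn1 at -1.08 ± 0.45 and Acta2 at 0.50 ± 0.52, with limma adjusted p-values of 0.698 to 0.858. Lcn2 at -1.75 ± 0.68, Ccl2 at -1.23 ± 0.39, Col3a1 at -0.34 ± 0.74 and Tgfb1 at 0.22 ± 0.34 did not pass (limma, adjusted p = 0.687, 0.594, 0.941 and 0.913). In the Notch pathway Notch1 at 1.64 ± 0.99, Notch2 at -0.35 ± 0.18, Notch3 at 0.12 ± 0.36, Notch4 at 0.23 ± 0.20, Jag1 at 0.11 ± 0.38, Hes1 at -0.49 ± 0.55, Hey1 at 0.55 ± 0.34 and Heyl at 0.57 ± 0.55 did not pass, with limma adjusted p-values from 0.737 to 0.968. Without Notch3-/- UUO replicate 1, 44 genes were called with a larger and 10 with a smaller response in Notch3-/- kidneys. That fit leaves only the 2 UUO arrays with high Xist, so sex and a different response cannot be told apart in it. Without Notch3-/- healthy replicate 1, which leaves 1 array in that group, Ifng differed by 3.44. Ifng was not well above background in Notch3-/- healthy kidneys.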

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

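Of the tests weighed here, only the 1 on signal near background was set down before its result was seen; all others, and the term for arrays with high Xist, were chosen after the results were seen.

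Lists whose response to obstruction differed between the genotypes are given as the median of the Notch3-/- minus the wild-type log2 fold changes. It was -1.60 for cell cycle genes and 1.15 for T and NK cell markers (camera, adjusted p = 1.19e-21 and 2.48e-12; adjusted p = 0.346 and 0.342 with an estimated correlation). It was 0.59 for endothelial markers, with 5 of 18 higher adjusted over the list alone (camera, adjusted p = 2.59e-07; adjusted p = 0.346 with an estimated correlation). Tubular injury markers stood at -0.75, with 4 of 26 lower adjusted over the list alone (camera, adjusted p = 4.23e-05; adjusted p = 0.504 with an estimated correlation). Podocyte and glomerular markers stood at 0.55 and interferon response genes at 0.44 (camera, adjusted p = 6.14e-05 and 0.000303; adjusted p = 0.346 and 0.851 with an estimated correlation). Chemokine receptors stood at 0.23, with 1 of 14 higher adjusted over the list alone (camera, adjusted p = 0.0479; adjusted p = 0.346 with an estimated correlation). The call of the injury list ended without wild-type healthy replicate 2, at -0.57, and that of the interferon list without Notch3-/- healthy replicate 1, at 0.14 (camera, adjusted p = 0.0986 and 0.516). That of the chemokine receptors ended without either wild-type healthy array, wild-type UUO replicate 1, Notch3-/- UUO replicate 3 or Notch3-/- healthy replicate 1 (camera, adjusted p = 0.0974, 0.0986, 0.0785, 0.0824 and 0.172). No list passed with fry. In the cell cycle, T and NK cell, endothelial and podocyte lists the genotypes differed mainly in healthy kidneys. Medians were 1.58, -0.73, -0.78 and -0.31 there, against 0.04, 0.27, -0.10 and -0.01 in obstructed kidneys. Injury and interferon lists differed more in obstructed kidneys, at -0.38 and 0.70 against 0.20 and 0.28. Chemokine receptors stood at 0.24 in obstructed and -0.21 in healthy kidneys.

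The first pattern is the set of genes called between the genotypes. A term for the 2 arrays with high Xist left the median difference of the 70 genes called in obstructed kidneys, Notch3 left out, at 0.968 of its size and kept 25 of the calls. That leaves sex open, since Notch3-/- UUO replicate 1 is then the only array of its group without high Xist and the genes were called with all 3 arrays. Of these genes 64 had the same direction in healthy kidneys, as both genotype and scan campaign would give, with a median difference in the called direction of 1.01 there against 1.84 in the obstructed kidneys they were chosen in; genotype and campaign cannot be told apart, since each genotype was scanned in a campaign of its own. Strain background around Notch3 stays open too: calls among the 200 nearest genes had an odds ratio of 1.7 (Fisher's exact test, two-sided p = 0.335; 95% interval 0.201 to 6.38). That rests on 2 of the 200 genes called between healthy groups and 0 between obstructed groups.

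The second pattern is the higher cell cycle signal in healthy kidneys without Notch3, with a median of 1.58. A scan campaign shift of equal size in both kidney states would appear in obstructed kidneys as well. There the median was 0.043, and the difference stayed between -1.96 and -1.22 with each array left out. A campaign effect of unlike size in healthy and obstructed kidneys stays open. Spike-in transcripts, added in fixed amounts, stood at 0.39 and 0.85 on wild-type and -0.18 and 0.02 on Notch3-/- healthy arrays. On UUO arrays the gap was wider, at 0.93 and 1.28 against -0.52 to -0.36. Signal near background would give random lists of like level such medians, but the highest of 10000 was 0.31. T and NK cells in the sample would bring their markers, and that list stood at -0.734; other leukocytes stay open, with medians of -0.04 for B cell, -0.10 for macrophage and 0.14 for neutrophil markers. What remains is a hypothesis of a difference between these arrays, which may be genotype, another difference between animals or an unequal campaign effect. The wild-type healthy arrays lay on slides of their own, and no biological cause was tested.

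The third pattern is Notch3-/- UUO replicate 1, which stood apart from the others of its group. Unobstructed tissue mixed in would bring all changes alike nearer to healthy kidneys. The share of obstructed signal places replicate 1 between the Notch3-/- healthy mean and the mean of replicates 2 and 3. Its genes were those called without replicate 1, a choice that can by itself draw the share of that array down. The median share was 0.546 over 73 matrix genes (quartiles 0.445 and 0.67) and 0.535 over 17 injury genes (0.342 and 0.636). For 95 tubule and oxidative phosphorylation genes that fell it was 0.611 (0.55 and 0.661). Over 103 immune genes it was 0.859 (0.682 and 1.14), so the lists that go with mixed-in tissue and the one that does not leave it open. Sex acting in both genotypes would give wild-type UUO arrays of like Xist level as low a matrix response, but these stood at 2.372 and 2.672 against 1.366. A weaker response of matrix, injury and tubule genes in that animal, or an effect of sex within Notch3-/- mice, stays open and was not tested.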

How the results depend on the processing

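Alternatives with a term for the arrays with high Xist, with these 2 arrays left out or with a crossed replicate block were chosen after seeing the data. A value counted as reversed only if its direction changed and it passed the threshold in the reported fit or the alternative. Changes of direction among values that passed in neither were not counted. Of 5423 values of named genes under alternatives, 4559 kept their side of the threshold without such a reversal, 721 lost the call, 139 gained it and 4 reversed. Of 4060 values of gene lists the numbers were 3654, 202, 202 and 2. Between 65.3% and 73.2% of spots lay well above background, which limits what dim genes can show, and each group had 2 or 3 arrays. The cause was not tested for any of the changes below, unless fewer arrays or a stricter threshold make it.

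The counts are given in the order wild-type UUO versus healthy (6179), Notch3-/- UUO versus healthy (6493), between UUO groups (71) and between healthy groups (122). The threshold of 0.01 gave 1677, 1316, 5 and 4, and fitting only the groups compared gave 3499, 3815, 603 and 0 (limma, smallest adjusted p = 0.284, with 2428 at an unadjusted p under 0.05). A 2-fold minimum gave 3975 and 3784 in the first pair. Slide as a random block gave 2406, 3 and 12 in all but the second, and the slide with both Notch3-/- groups, or slide as a fixed block, gave 787 in the second. Array weights gave 11440, 4374 and 4 in all but the first. Between UUO groups quantile normalization gave 141, normexp 213, both 419, the values of the authors 298 and probes well above background on all arrays 131. Between healthy groups normexp with quantile normalization gave 76, the values of the authors 63, no filter 78 and trended robust moderation 236. The term for high Xist gave 1150 in the second and 131 between UUO groups, and leaving those arrays out gave 402, 0 (limma, smallest adjusted p = 0.0576, with 3404 at an unadjusted p under 0.05) and 3 in all but the first. The difference of responses, with 0 calls in limma and 1705 genes at an unadjusted p under 0.05, had 2 with quantile normalization.

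The replicate block gave 2586, 924, 0 (limma, smallest adjusted p = 0.0879, with 2422 at an unadjusted p under 0.05) and 1, and the crossed replicate block 2624, 915, 4 and 3. Deviations of same-numbered arrays correlated at 0.097 in wild-type, 0.158 and 0.07 in Notch3-/-, and -0.113 to -0.173 across genotypes. Where both groups had 2 arrays, both replicate numbers give the same value by construction. Among Notch3-/- arrays, Xist and Ddx3y stood at 0.18 and -3.80 on UUO replicate 2, but at -6.52 and 0.205 on healthy replicate 2. The crossed block joins UUO replicate 2 to healthy replicate 1, at -5.71 and 0.42. These values argue against 1 animal behind the arrays so joined. For the remaining arrays the numbers are not shown to pair them.

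Leaving out single arrays gave 1287 to 7451, 1226 to 8643, 1 to 633, 1 to 217 and, for the difference of responses, 0 to 54 genes. The lists called by camera (26, 28, 10, 15 and 7) ranged over 25 to 27, 27 to 31, 8 to 15, 10 to 20 and 6 to 17. With an estimated correlation 0 lists passed in each comparison (smallest adjusted p 0.146, 0.104, 0.754, 0.35 and 0.342). With fry 0, 5 and 0 passed in the last 3. Both Xist alternatives gave 20 lists between UUO groups and 14 for the difference of responses, where normexp gave 11, no filter 12 and slide as a random block 11.

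Reversed values were Dll4 at 0.00 (Notch3-/- UUO versus healthy), Lep at 0.006 (between UUO groups) and Il7r at 0.22 (between healthy groups) with normexp, and Dscaml1 at -1.21 (between UUO groups) with the mean of its probes. The sex-dependent genes stood at 0.55 with the term for high Xist (between UUO groups), and the median of oxidative phosphorylation genes, for the difference of responses, ranged from -0.208 without Notch3-/- UUO replicate 1 to 0.13 without replicate 2.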

Other observations

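Further lists moved with obstruction in wild-type kidneys. Of 30 complement and coagulation genes 21 rose and 1 fell (23 and 1 adjusted over the list alone), and of 31 genes of NF-kappaB and toll-like receptor signalling 21 rose (23 rose and 1 fell adjusted over the list alone), including the receptor Tlr2 at 3.90 ± 0.21. Of 26 peroxisome and antioxidant genes 12 fell and 1 rose (16 and 1 adjusted over the list alone), with catalase, Cat, at -1.64 ± 0.26. Camera adjusted p-values were 9.79e-09, 2.59e-10 and 2.15e-06, and adjusted p = 0.146, 0.146 and 0.192 with an estimated correlation. In Notch3-/- kidneys 20 of 30 complement genes rose (24 rose and 1 fell adjusted over the list alone), and 20 of 26 peroxisome genes fell (22 adjusted over the list alone). Their camera adjusted p-values were 7.12e-12 and 3.62e-07, and 0.111 and 0.164 with an estimated correlation. B cell and plasma cell markers passed in neither genotype (camera, adjusted p = 0.158 and 0.145).

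The spike-in transcripts, added in fixed amounts as labelling controls, stood at 0.39 to 1.28 relative to the 75th percentile on the wild-type arrays and at -0.52 to 0.02 on the Notch3-/- arrays.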
